A study of Homo sapiens with 9 samples.

How the data were processed

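Total RNA was sequenced from HCT116, an established human colorectal cancer cell line, after lipid transfection with a control siRNA or with 1 of 2 siRNAs directed against EXOSC10-AS1, a long non-coding RNA gene that lies antisense to EXOSC10. Per the labels, 3 libraries were made for each of the 3 groups, RNA was extracted with Trizol, library preparation followed Illumina's standard protocol, and all 9 libraries share the batch entry of day 3. The siRNA sequences and the dose were not used here. Groups were taken from the sample titles and treatments, and libraries are named below by group and replicate number. The titles and the batch entry do not say whether the libraries of a group came from separate transfections. The spread between them may therefore cover repeats within a single experiment only.

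The authors deposited 1 table of raw read counts per Ensembl gene identifier, and the labels describe these values as raw counts. The build hg19 is given per the submitters' processing notes. The aligner, the counting tool, the annotation, the handling of multiply mapped reads and the counting strand are not given in the sources used here. The table held 61806 gene identifiers with whole-number values, and every identifier was kept as it stands in the table. Symbols were taken from a table of Ensembl identifiers and symbols, which matched 61757 identifiers and left 49 without a symbol, and those 49 held 0.0158% of all counts. The reference annotation at hand is on a newer build, so no coordinates are printed. It served only for gene names, for which genes neighbour or overlap each other, and for the GC content and length of the longest transcript of each gene.

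Depth ranged from 56.8 to 66.5 M deposited counts per library, and 25829 identifiers were at 0 in all 9 libraries. Counts of 4 and 8 were more frequent than their neighbours. A library held on average 803 genes with a count of 3, 1357 with a count of 4 and 497 with a count of 5, and 426, 556 and 298 genes with counts of 7, 8 and 9. The counts may therefore not all be independent fragments, and the reads carried no molecular identifiers, so floors cover counting error only. The SDs and standard errors given below rest on the spread between libraries. A floor of 3 counts was used where a library was at 0.

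Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with TMM factors. All 9 libraries entered 1 model of group means without a replicate block. Each gene's spread was thus taken as equal in all groups, although the libraries of each siRNA lay less close together than the controls. Adjusted p values therefore depend on which groups share a fit. Genes were filtered by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20868 genes with 99.96% of the counts. The common biological coefficient of variation was 20.0%. Adjusted p values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were each siRNA against control, siRNA 2 against siRNA 1, and the average of both siRNAs against control. Values per group are means with SD over 3 libraries, in CPM computed from the deposited counts. Each count was scaled to the library's total over the tested genes times its TMM factor. Log2 fold changes are given with the standard error implied by the F statistic.

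36 gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and, beside it, an estimated correlation. The lists were the EXOSC10-AS1 locus, the RNA exosome, snoRNA host genes, p53 targets, G1/S replication, G2/M mitosis, MYC targets, ribosomal proteins, the mitochondrial genome, oxidative phosphorylation, glycolysis, hypoxia, cholesterol synthesis, fatty acid synthesis, the ATF4 response, the unfolded protein response, heat shock, the interferon response, NF-kB inflammation, Wnt targets, MAPK output, TGF-beta and YAP targets, mesenchymal genes, epithelial genes, intestinal differentiation, the NRF2 response, apoptosis, autophagy and lysosome, the mTOR pathway, polyamines, DNA repair, histones and the RNAi machinery, with fibroblast, leukocyte, and neural and liver markers for other cell types. Adjusted p values of lists are over the lists within a comparison, and list members are also counted with their p values adjusted over the list alone. Fry was run as an alternative.

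The grouping, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named EXOSC10-AS1 and its neighbours. For each pairwise comparison it named the 5 genes with the largest rise and the 5 with the largest fall among called genes with an average log2 CPM of at least 2 and no overlap between the groups' libraries. For genes called with both siRNAs in the same direction it named 10 each way by the smaller of the 2 fold changes, with all knockdown libraries beyond all controls. It also named up to 4 members of each list with the lowest adjusted p. XIST and Y-linked genes were left out. Some single-gene results are not reported here. With 3 libraries against 3, chance alone puts every library of one group beyond the other for 10% of genes.

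The alternatives were RLE, upper quartile and total count scaling, no filter, a stricter filter of a CPM of 1 in 3 libraries, DESeq2 1.42.0, limma-voom, fits of only the groups compared, a replicate block, a fold change minimum and each library left out in turn. Alternatives added after the data were seen removed a trend of expression on GC content (a natural spline with 5 inner knots per library, put into the offsets, alone, with length, or with the replicate block) or left out libraries that stood apart. Both comparisons against control share the control libraries. To gauge this, 20 sets of all 9 libraries, the controls included, were simulated from each gene's control mean with no change between groups. Splits of the libraries into groups of the same sizes were counted with the real one included, 10 for each pair of groups and 84 for both siRNAs as 1 group against control.

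The procedure was tested on simulated counts for siRNA 1 against control over 20868 genes, where changed genes had an average log2 CPM of at least 2. Of genes changed by a log2 fold change of 0.5, 1 and 2, the test called 25.4%, 86.6% and 100%, with 7 calls among unchanged genes. In simulated counts for siRNA 2 against control over the same genes, a linear GC trend was put into all siRNA 2 libraries. With no other change between these groups it gave 941 calls, and removal of the trend gave 0. The real trend differed between replicates of a group, which was not simulated, so this shows only that a trend of the simulated form can be removed.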

Results

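RNA-seq counts were analysed from 9 libraries of HCT116 colorectal cancer cells, 3 each with a control siRNA, siRNA 1 and siRNA 2 against the long non-coding RNA EXOSC10-AS1. The control libraries held 60.0, 56.8 and 62.1 M counts, the siRNA 1 libraries 61.1, 64.4 and 66.5 M, and the siRNA 2 libraries 61.8, 59.8 and 63.9 M. Each siRNA was compared with control to ask which genes change when EXOSC10-AS1 is targeted. The siRNAs were compared with each other because changes that follow the targeted RNA should be common to both. Values after ± are standard errors of log2 fold changes unless SD is stated, and every group has 3 libraries.

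EXOSC10-AS1 (ENSG00000230337) had few counts in every group. The control libraries had 26, 4 and 14 counts, the siRNA 1 libraries 4, 0 and 0, and the siRNA 2 libraries 5, 13 and 0. Mean levels were 0.243 ± 0.182 CPM in control, 0.0219 ± 0.0379 with siRNA 1 and 0.0991 ± 0.109 with siRNA 2 (SD, n = 3), and 3 counts correspond to between 0.0451 and 0.0529 CPM in these libraries. The fitted log2 change was -3.40 ± 1.45 with siRNA 1 (adjusted p = 0.19) and -1.29 ± 1.24 with siRNA 2 (adjusted p = 0.55). A loss of EXOSC10-AS1 was therefore not called with either siRNA after adjustment over the genes tested. By the same edgeR test its unadjusted p was under 0.05 with siRNA 1, and not with siRNA 2. These values rest on few counts. Exons of EXOSC10-AS1 overlap EXOSC10 on the opposite strand, and the counting strand is not given in the sources used here, so reads of the one may have been counted for the other. EXOSC10 itself (ENSG00000171824), a catalytic subunit of the nuclear RNA exosome, stood at 90.9 ± 2.89 CPM in control, 94.7 ± 7.51 with siRNA 1 and 99.5 ± 1.21 with siRNA 2 (SD). Its log2 changes were 0.06 ± 0.07 (adjusted p = 0.68) and 0.13 ± 0.07 (adjusted p = 0.27).

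Among 19 measured genes of the EXOSC10-AS1 locus, DFFA, which encodes an inhibitor of the apoptotic DNase, and the kinase gene MTOR were called with both siRNAs. DFFA rose by 0.30 ± 0.07 with siRNA 1 (adjusted p = 0.023) and by 0.44 ± 0.07 with siRNA 2 (adjusted p = 0.0028), and MTOR by 0.27 ± 0.07 (adjusted p = 0.046) and 0.43 ± 0.07 (adjusted p = 0.0042). The transcription factor gene CASZ1 fell by 0.54 ± 0.11 with siRNA 2 (adjusted p = 0.012) and was 0.63 lower with siRNA 2 than with siRNA 1 in log2 terms (-0.63, adjusted p = 0.0043). SRM, a polyamine synthesis gene beside EXOSC10, was not called with siRNA 1 (0.58 ± 0.16, adjusted p = 0.063). With siRNA 1, the call of DFFA was lost without each control library or siRNA 1 replicate 3, with adjusted p up to 0.122 without control replicate 3, and that of MTOR without each control or siRNA 1 replicates 2 or 3, up to 0.176 without control replicate 2. The CASZ1 call with siRNA 2 was lost without control replicates 2 or 3 or siRNA 2 replicates 2 or 3, up to 0.0664 without control replicate 2. DFFA, MTOR and CASZ1 overlap genes on the opposite strand, and the locus list as a whole was not called in any comparison.

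The libraries of each siRNA did not lie equally close together. On the first principal component of log2 CPM, which held 25.9% of the variance, controls lay between -8.01 and -4.21, siRNA 1 replicate 1 at -70.4 against -24.3 and -28.8 for its replicates, and siRNA 2 replicate 1 at 19.2 against 63.5 and 59.1. Expression followed GC content across 12234 genes in 3 libraries. The correlation across genes, which are not independent replicates, was 0.549 in siRNA 1 replicate 1, -0.509 in siRNA 2 replicate 2 and -0.516 in siRNA 2 replicate 3, against -0.0327 to 0.0465 in controls, -0.0813 and -0.0756 in the other siRNA 1 libraries and -0.169 in siRNA 2 replicate 1. From the lowest to the highest 10% of genes by GC content, the median difference from control ran from -0.70 to 0.24 log2 units in siRNA 1 replicate 1 and from 0.20 to -0.51 in siRNA 2 replicate 2. Mitochondrial transcripts made up 8.28 ± 0.058% of counts in control, 8.54 ± 0.032% with siRNA 1 and 8.95 ± 0.194% with siRNA 2 (SD, n = 3). Because the trend differed between the groups, medians with it removed per library are given beside the gene groups below.

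**Figure D1:**
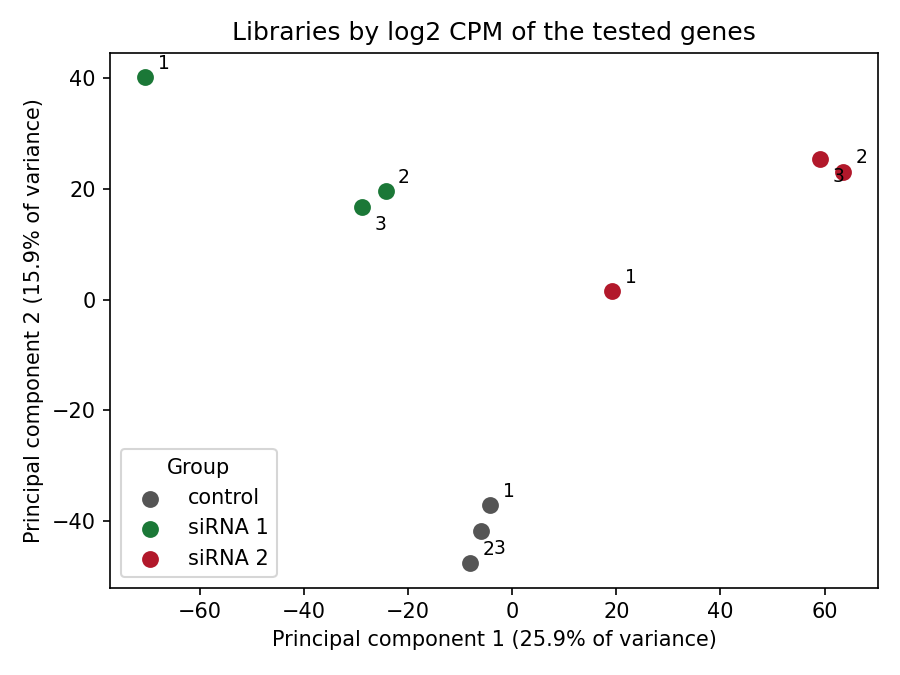
Principal components 1 and 2 of log2 CPM for the 9 libraries, numbered by replicate and coloured by group, with the percent of variance on each axis. The controls lie together, while siRNA 1 replicate 1 lies at -70.4 on component 1 and siRNA 2 replicates 2 and 3 at 63.5 and 59.1.

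**Figure D2:**
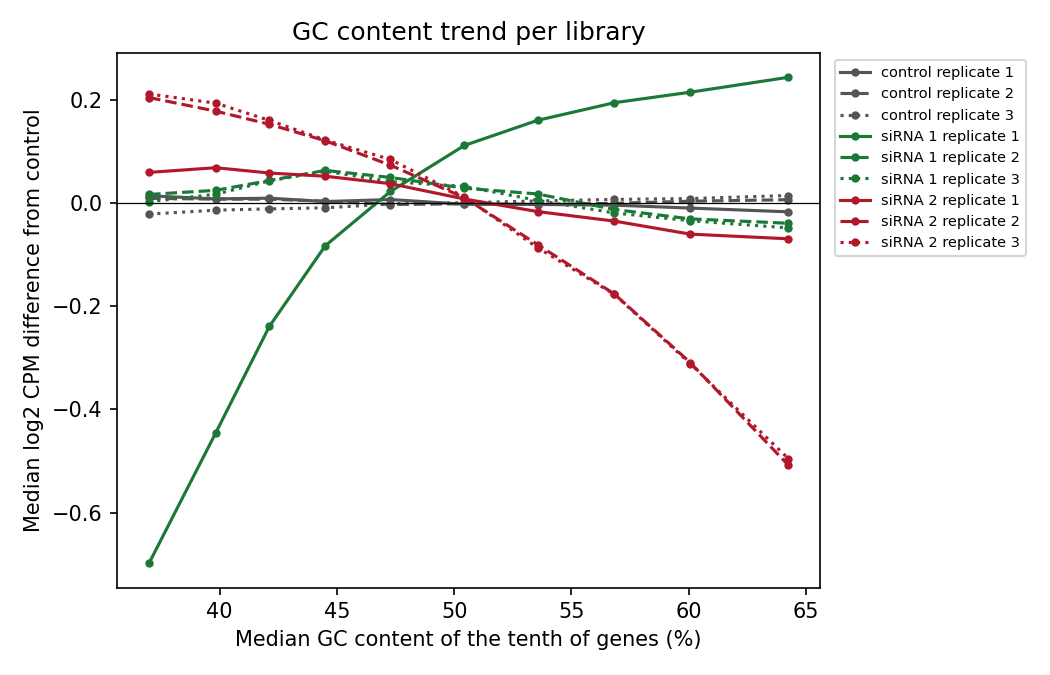
Median log2 CPM difference from the control mean (y axis) against the median GC percent of each 10% of genes (x axis), 1 line per library. siRNA 1 replicate 1 rises from -0.70 to 0.24 and siRNA 2 replicates 2 and 3 fall from 0.20 and 0.21 to -0.51 and -0.50, while the other lines are flatter.

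With siRNA 1, SCG2, a granin of secretory granules, rose from 8.81 ± 0.436 to 24.0 ± 0.933 CPM (SD, n = 3), a log2 change of 1.45 ± 0.11 (adjusted p = 0.00020). S100A14, a calcium-binding S100 protein gene, rose from 35.7 ± 1.33 to 92.7 ± 5.98 CPM (SD), a log2 change of 1.38 ± 0.07 (adjusted p = 7.3e-05). The lysosomal hydrolase gene AGA rose by 1.32 ± 0.12, GRAMD2A by 1.24 ± 0.16 and RGS16, a regulator of G protein signalling, by 1.38 ± 0.27 on the log2 scale. SPARC, a matrix-associated glycoprotein gene, fell by 2.32 ± 0.20 (adjusted p = 0.00036), from 4.70 ± 0.443 to 0.938 ± 0.256 CPM (SD). RPE65, a retinoid isomerase gene, fell by 1.93 ± 0.14, the simple-epithelial keratin gene KRT7 by 1.70 ± 0.12, the muscle intermediate filament gene DES by 1.65 ± 0.25 and the troponin gene TNNC1 by 1.58 ± 0.37. SPARC, KRT7 and DES overlap genes on the opposite strand. In all, 777 genes rose and 701 fell, of which 59 and 114 changed at least 2-fold, and 2025 rose and 2052 fell after GC correction. The count of 1478 fell to 476, 439 and 452 without control replicates 1, 2 and 3 and to 890 and 845 without siRNA 1 replicates 2 and 3, and was 2538 without siRNA 1 replicate 1. The calls of RGS16 (adjusted p 0.0623 without control replicate 3, and lost without control replicate 2) and TNNC1 (0.116 without control replicate 1, and lost without each other control and siRNA 1 replicates 2 or 3) were not kept.

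Genes of DNA replication rose together with siRNA 1. Of 30 G1/S replication genes, 17 rose and 24 did when adjusted over the list alone, with a median of 0.38 (camera, adjusted p = 1.7e-15). The phosphatase gene CDC25A rose by 0.76 ± 0.07, the ribonucleotide reductase gene RRM2 by 0.63 ± 0.08, the replication factor gene CDC45 by 0.63 ± 0.08 and the sliding clamp gene PCNA by 0.47 ± 0.06. Of 30 G2/M mitosis genes, 3 rose, 5 adjusted over the list alone, among them BIRC5 (0.38 ± 0.06) and CCNB2 (0.40 ± 0.06). The mitosis list was called (median 0.14, adjusted p = 0.00024; adjusted p = 0.088 with an estimated correlation). Of 20 DNA repair genes, 5 rose, 6 adjusted over the list alone, including EXO1 (0.60 ± 0.07) and FANCI (0.39 ± 0.06). The repair list was called (median 0.23, adjusted p = 0.00040; adjusted p = 0.26 with an estimated correlation). Of 30 MYC targets, 5 rose and 15 did adjusted over the list alone (median 0.19, adjusted p = 1.4e-06), including the nucleolar gene NOLC1 (0.65 ± 0.06) and the polyamine enzyme gene ODC1 (0.64 ± 0.07). After GC correction the medians were 0.35, 0.16, 0.32 and 0.19, and these 4 lists were still called.

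Targets of ATF4, the transcription factor of the amino acid stress response, were also higher with siRNA 1. Of 23 measured, 13 rose and 16 did adjusted over the list alone, with a median of 0.43 (adjusted p = 3.3e-11). ASNS, which makes asparagine, rose by 1.04 ± 0.07, the serine synthesis gene PSAT1 by 0.65 ± 0.07, the mitochondrial enzyme gene PCK2 by 1.15 ± 0.13 and the transporter subunit gene SLC3A2 by 0.74 ± 0.09. Of 19 NRF2 targets, 9 rose and 12 did adjusted over the list alone (median 0.37, adjusted p = 3.4e-06), among them the quinone reductase gene NQO1 (0.71 ± 0.05), the ferritin genes FTH1 (0.53 ± 0.07) and FTL (0.65 ± 0.09), which have many processed copies in the genome, and TXNRD1 (0.37 ± 0.05). Of 15 heat shock genes, 8 rose and 11 did adjusted over the list alone (median 0.29, adjusted p = 6.8e-08), with HSP90AB1 at 0.36 ± 0.04 and HSPA8 at 0.37 ± 0.05. Of 25 nuclear oxidative phosphorylation genes, 1 rose and NDUFA4 fell by 0.70 ± 0.10, and 7 rose adjusted over the list alone. That list was called higher (median 0.18, adjusted p = 0.00055; adjusted p = 0.46 with an estimated correlation). Without the GC trend the 4 medians were 0.42, 0.35, 0.34 and 0.16, all still called.

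Other signalling and metabolic targets were lower with siRNA 1. Of 20 TGF-beta and YAP targets, 9 fell and 1 rose, or 11 and 2 adjusted over the list alone (median -0.38, adjusted p = 0.00014), including the receptor gene AXL (-0.73 ± 0.07), ID2 (-0.81 ± 0.09), AMOTL2 (-0.61 ± 0.07) and CCN2 (-0.96 ± 0.13). ANKRD1, at 0 in all controls, has no fold, and the median was -0.39 without it. Of 12 mesenchymal genes, 3 fell and 4 did adjusted over the list alone (median -0.37, adjusted p = 0.00032). Among them were SPARC and S100A4 (-0.84 ± 0.11). Of 24 cholesterol synthesis genes, 6 fell and 1 rose, or 9 and 1 adjusted over the list alone (median -0.14, adjusted p = 0.00048), with SQLE at -0.47 ± 0.06 and the sterol carrier gene STARD4 at -1.23 ± 0.23. Of 20 hypoxia targets, 5 fell and 1 rose, or 8 and 1 adjusted over the list alone, including the glucose transporter gene SLC2A3 (-0.85 ± 0.06) and BNIP3 (-0.64 ± 0.08). The hypoxia list was called (median -0.24, adjusted p = 0.00055; adjusted p = 0.088 with an estimated correlation). Of 16 NF-kB targets, 4 fell, 6 adjusted over the list alone, including the NF-kB inhibitor gene NFKBIA (-0.85 ± 0.11). The NF-kB list was called (median -0.37, adjusted p = 0.00040; adjusted p = 0.081 with an estimated correlation). Of 18 MAPK output genes, 4 fell and 1 rose, or 6 and 1 adjusted over the list alone, including CCND1 (-0.86 ± 0.09), SPRY4 (-0.45 ± 0.06) and DUSP5 (-0.56 ± 0.09). The MAPK list was called (median -0.20, adjusted p = 0.00055; adjusted p = 0.10 with an estimated correlation). The GC-corrected medians of the 6 lists were -0.43, -0.40, -0.17, -0.25, -0.40 and -0.23, all still called.

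The remaining lists were not called with siRNA 1. Of 24 exosome genes 0 were called by edgeR, 4 had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 1 (list median -0.02, adjusted p = 0.90). Of 28 p53 targets, 5 rose and 2 fell, or 9 and 3 adjusted over the list alone (median 0.14, adjusted p = 0.14), with BTG2 at 0.47 ± 0.07 and CCNG1 at -0.87 ± 0.13. Of 21 snoRNA host genes SNHG5 fell by 0.59 ± 0.09 (list median -0.03, adjusted p = 0.60), and of 30 ribosomal protein genes, which have many pseudogenes, RPL15 fell by 0.30 ± 0.05 (list median 0.07, adjusted p = 0.14). Epithelial genes had a median of 0.20 (7 of 20 rose, 1 fell, adjusted p = 0.073), with GRHL2 at 0.68 ± 0.11, and Wnt targets 0.15 (adjusted p = 0.93), with BMP4 at 0.68 ± 0.07. Medians were 0.01 for the mitochondrial genome (adjusted p = 0.60), 0.01 for glycolysis (adjusted p = 0.92), -0.15 for fatty acid synthesis (adjusted p = 0.46), -0.04 for the unfolded protein response (adjusted p = 0.72) and -0.04 for the interferon response (adjusted p = 0.80). They were 0.01 for apoptosis (adjusted p = 0.92), where MCL1 fell by 0.75 ± 0.08, 0.03 for autophagy and lysosome (adjusted p = 0.69), -0.07 for the mTOR pathway (adjusted p = 0.91), 0.03 for polyamines (adjusted p = 0.60) and -0.27 for histones (adjusted p = 0.50). The RNAi machinery had a median of -0.08 (adjusted p = 0.60), with 0 of 13 called by edgeR, 5 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The intestinal differentiation list had 7 of 20 genes measured (median -0.14, adjusted p = 0.69, and a median of 0.09 without MUC2, which was at 0 with siRNA 2), and fibroblast markers 3 of 10 (median -0.30, adjusted p = 0.42). Leukocyte markers had 7 of 10 (median -0.46, adjusted p = 0.95), and neural and liver markers 5 of 10 (median 0.03, adjusted p = 0.42). Median, mean and test differed in sign for the locus, mitochondrial genome, Wnt, apoptosis, intestinal, leukocyte, and neural and liver lists.

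With siRNA 2, APOBEC3G, a cytidine deaminase gene of antiviral defence, rose from 1.52 ± 0.520 to 10.6 ± 0.200 CPM (SD, n = 3), a log2 change of 2.80 ± 0.27 (adjusted p = 0.00032). IGFBP3, a binding protein of insulin-like growth factors, rose from 7.08 ± 0.776 to 31.2 ± 2.65 CPM (SD), a log2 change of 2.14 ± 0.13 (adjusted p = 4.2e-05). The non-coding RNA gene LINC02331 rose by 1.97 ± 0.18, the integrin gene ITGB8 by 1.95 ± 0.47 and MYBPH, a myosin binding protein gene, by 1.83 ± 0.11. CD68, a lysosomal glycoprotein gene, fell by 1.90 ± 0.19 (adjusted p = 0.00039), from 18.5 ± 3.03 to 4.97 ± 1.36 CPM (SD). TMEM158 fell by 1.77 ± 0.32, the transcription factor gene CEBPB by 1.66 ± 0.32, the cyclin-dependent kinase inhibitor gene CDKN1C by 1.59 ± 0.20 and the readthrough gene RPL17-C18orf32 by 1.59 ± 0.22. TMEM158, CEBPB and CDKN1C are rich in GC, and their log2 changes were -1.39, -1.30 and -1.27 with the GC trend removed. In siRNA 2 replicates 1, 2 and 3, TMEM158 stood at 54.2, 20.6 and 20.6 CPM and CEBPB at 44.8, 17.5 and 16.8 CPM. CD68 and RPL17-C18orf32 share exons with genes on the same strand, and ITGB8 and CEBPB overlap genes on the opposite strand, so their counts are uncertain. In all, 1284 genes rose and 1588 fell, of which 158 and 182 changed at least 2-fold. This balance turned after GC correction, with 2349 up and 2069 down, and with upper quartile factors, with 53.1% of the called genes up. The count of 2872 fell to 1105, 1080 and 1094 without control replicates 1, 2 and 3 and to 1093 and 1099 without siRNA 2 replicates 2 and 3, and was 4386 without siRNA 2 replicate 1. ITGB8 was not called without control replicates 2 or 3 or siRNA 2 replicates 2 or 3 (adjusted p up to 0.0783 without siRNA 2 replicate 3).

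Sterol synthesis, hypoxia targets and glycolysis were lower with siRNA 2. Of 24 cholesterol synthesis genes, 17 fell and 19 did adjusted over the list alone, with a median of -0.46 (adjusted p = 1.2e-12). SREBF2, the transcription factor gene of this pathway, fell by 1.18 ± 0.10, HSD17B7 by 0.90 ± 0.10 and MVK by 0.78 ± 0.09. Of 20 hypoxia targets, 14 fell and 16 did adjusted over the list alone (median -0.52, adjusted p = 4.1e-11), among them the angiogenic factor gene VEGFA (-0.75 ± 0.06), ANKRD37 (-1.33 ± 0.12) and BNIP3L (-1.34 ± 0.13). Of 20 glycolysis genes, 15 fell, or 18 with 1 that rose adjusted over the list alone, including ENO2 (-0.93 ± 0.06), PFKFB3 (-1.12 ± 0.09) and PGK1 (-0.51 ± 0.06). The glycolysis list was called (median -0.48, adjusted p = 1.2e-12; adjusted p = 0.13 with an estimated correlation). Of 23 ATF4 targets, 13 fell and 14 did adjusted over the list alone. By adjusted p the lowest were the stress transcription factor gene DDIT3 (-1.38 ± 0.10), the amino acid transporter gene SLC7A5 (-1.36 ± 0.11) and STC2 (-0.86 ± 0.07). CEBPB had the largest fall (-1.66 ± 0.32). The ATF4 list was called (median -0.30, adjusted p = 1.2e-07; adjusted p = 0.064 with an estimated correlation). With the GC trend removed the medians were -0.51, -0.49, -0.36 and -0.32, and all 4 lists were still called.

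6 further lists were lower with siRNA 2, each losing its call with an estimated correlation. Of 16 NF-kB targets, 6 fell, 7 adjusted over the list alone, including NFKB2 (-0.70 ± 0.10), NFKBIA (-0.77 ± 0.11) and TNFAIP3 (-0.79 ± 0.12). Its median was -0.57 (adjusted p = 0.00011; adjusted p = 0.064 with an estimated correlation). Of 20 epithelial genes, 8 fell and 1 rose, or 12 and 1 adjusted over the list alone, with ELF3 at -0.76 ± 0.08. The epithelial median was -0.26 (adjusted p = 0.00096; adjusted p = 0.11 with an estimated correlation). Of 19 autophagy and lysosome genes, 8 fell and 1 rose, or 9 and 1 adjusted over the list alone, with the protease gene CTSB at -0.45 ± 0.07. The median was -0.27 (adjusted p = 0.0013; adjusted p = 0.064 with an estimated correlation). Of 30 ribosomal protein genes, 9 fell and 13 did adjusted over the list alone, with a median of -0.22 (adjusted p = 6.1e-06; adjusted p = 0.53 with an estimated correlation). Of 14 fatty acid synthesis genes, 4 fell and 1 rose, or 6 and 1 adjusted over the list alone, with ACSS2 at -0.64 ± 0.06 and ME1 at 0.80 ± 0.10. The fatty acid list had a median of -0.13 (adjusted p = 0.031; adjusted p = 0.11 with an estimated correlation). Of 18 mTOR pathway genes, 5 fell and MTOR rose, or 7 and 1 adjusted over the list alone, with a median of -0.22 (adjusted p = 0.029; adjusted p = 0.11 with an estimated correlation). Medians with the GC trend removed were -0.34, -0.19, -0.16, -0.20, -0.21 and -0.14, and the mTOR list was then not called (adjusted p = 0.11). The fatty acid list was not called without siRNA 2 replicate 1 (adjusted p = 0.105) and the mTOR list not without control replicate 3 (adjusted p = 0.0569).

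Heat shock, MYC, mitotic, mitochondrial and interferon lists were higher with siRNA 2. Of 15 heat shock genes, 8 rose and 9 did adjusted over the list alone (median 0.36, adjusted p = 4.3e-07), including HSPA8 (0.55 ± 0.05), HSPA4 (0.56 ± 0.06), HSP90AA1 (0.74 ± 0.08) and HSPH1 (0.76 ± 0.08). Of 30 MYC targets, 8 rose, or 8 with 3 that fell adjusted over the list alone, among them NOLC1 (0.65 ± 0.06), POLR1B (0.54 ± 0.09) and NCL (0.31 ± 0.05). The MYC list had a median of 0.18 (adjusted p = 0.0016; adjusted p = 0.064 with an estimated correlation). Of 30 G2/M mitosis genes, 8 rose, or 10 with 1 that fell adjusted over the list alone, including the cyclin genes CCNB1 (0.53 ± 0.07) and CCNB2 (0.46 ± 0.06) and the kinetochore gene CENPF (0.66 ± 0.11). The mitosis list had a median of 0.17 (adjusted p = 3.0e-05; adjusted p = 0.065 with an estimated correlation). Of 25 interferon response genes, 7 rose and 3 fell, or 10 and 3 adjusted over the list alone, with IFIT1 at 1.41 ± 0.13, IFIT2 at 1.51 ± 0.19 and OAS3 at 0.60 ± 0.08, against STAT2 at -0.51 ± 0.07. The interferon list was called (median 0.42, adjusted p = 0.0043; adjusted p = 0.064 with an estimated correlation), and not without both siRNA libraries numbered 1 (adjusted p = 0.054). Of 13 genes of the mitochondrial genome, 5 rose, or 6 with 1 that fell adjusted over the list alone, including MT-ND5 (0.37 ± 0.04) and MT-ND1 (0.36 ± 0.06). The mitochondrial genome list had a median of 0.12 (adjusted p = 0.0064; adjusted p = 0.065 with an estimated correlation). With the GC trend removed, the medians of the 5 lists were 0.36, 0.22, 0.13, 0.45 and 0.04, and the mitochondrial genome list was then not called (adjusted p = 0.57). G1/S replication (median 0.08, adjusted p = 0.066), p53 targets (median 0.02, adjusted p = 0.65), exosome genes (median 0.08, adjusted p = 0.46) and NRF2 targets (median -0.12, adjusted p = 0.53) were not called.

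**Figure D3:**
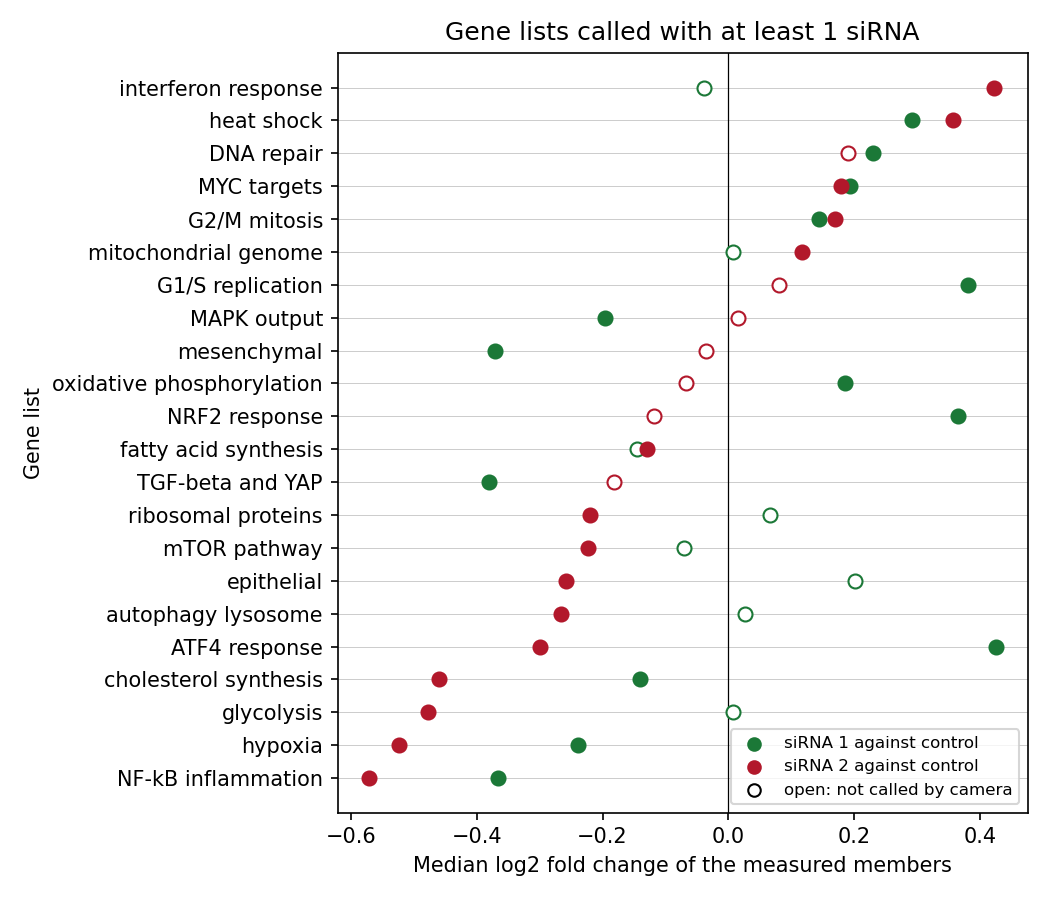
Median log2 fold change of the measured members of each gene list (x axis) for siRNA 1 and siRNA 2 against control, with open symbols for lists not called by camera at the preset correlation. The ATF4 response lies at 0.43 with siRNA 1 and -0.30 with siRNA 2, while cholesterol synthesis lies at -0.14 and -0.46.

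Among the lists called between the siRNAs at the preset correlation, the ATF4 response had the largest median difference. Of 23 measured ATF4 targets, 17 were lower with siRNA 2 than with siRNA 1, or 18 with 1 higher adjusted over the list alone, with a median of -0.91 (adjusted p = 3.5e-13; adjusted p = 0.038 with an estimated correlation). Against control, 10 members rose with siRNA 1 and fell with siRNA 2, and 0 were called in the same direction with both. These were CHAC1, a glutathione-degrading enzyme gene, at 0.90 ± 0.16 and -1.36 ± 0.16, SLC7A5 at 0.75 ± 0.11 and -1.36 ± 0.11, DDIT3 at 0.39 ± 0.10 and -1.38 ± 0.10, ASNS at 1.04 ± 0.07 and -0.68 ± 0.07, and SLC3A2 at 0.74 ± 0.09 and -0.66 ± 0.09. The others were ATF3 at 0.51 and -0.57, PHGDH at 0.47 and -0.59, PSAT1 at 0.65 and -0.26, ATF4 at 0.32 and -0.30, and SHMT2 at 0.28 and -0.26. Both calls of ASNS, SLC7A5, SLC3A2 and ATF3 held whichever 1 library was left out. The 10 members were 4, 5 and 4 without control replicates 1, 2 and 3, 8 and 7 without siRNA 1 replicates 2 and 3, and 6 without siRNA 2 replicate 2 or 3. Without siRNA 1 replicate 1 they were 12, beside 1 called in the same direction. Calls with siRNA 1 were lost for DDIT3 (adjusted p 0.151 without control replicate 1), PHGDH (0.106 without control replicate 1), ATF4 (0.106 without control replicate 2), SHMT2 (0.166 without control replicate 2) and CHAC1 (0.0527 without control replicate 1), and calls with siRNA 2 for PSAT1 (0.146 without control replicate 1), SHMT2 (0.150 without control replicate 3) and ATF4 (0.0901 without control replicate 3), among other libraries. DDIT3 shares exons with a gene on the same strand and SLC7A5 overlaps one on the opposite strand. With the GC trend removed the list median between the siRNAs was -0.90.

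**Figure D4:**
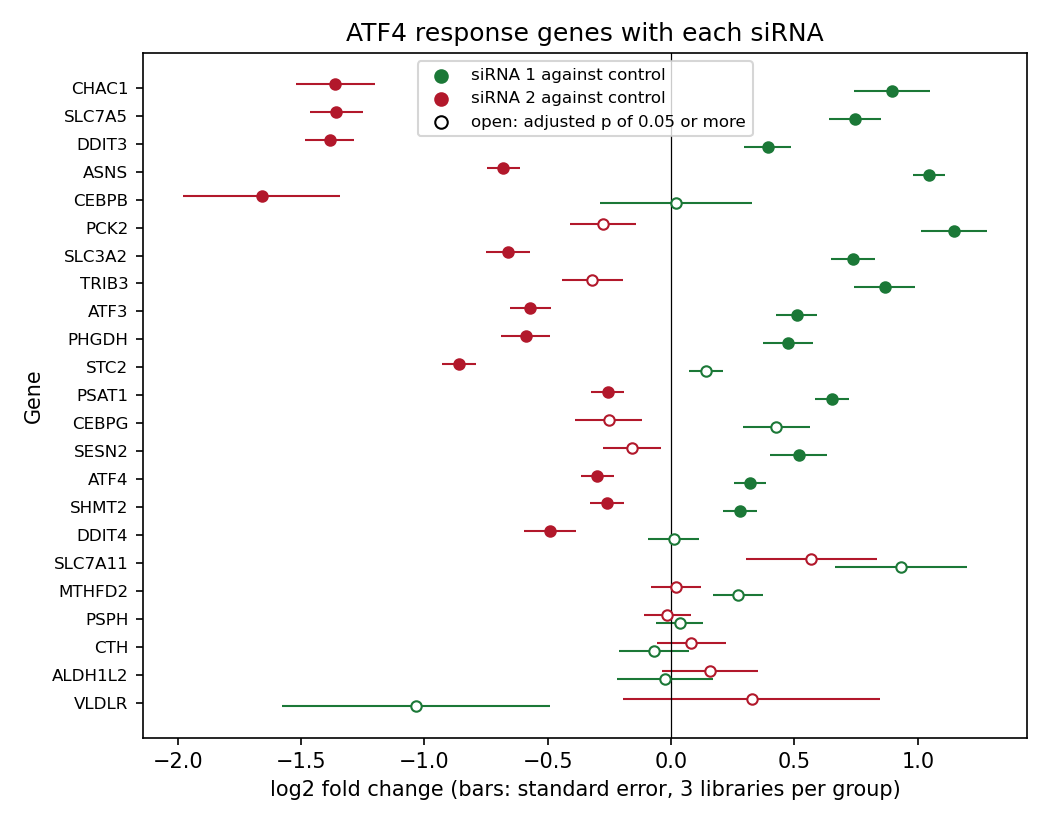
Log2 fold change against control with standard error bars (x axis) for the 23 measured genes of the ATF4 list, with siRNA 1 and siRNA 2 as separate points and open symbols for an adjusted p of 0.05 or more. CHAC1, SLC7A5, DDIT3, ASNS and SLC3A2 lie above 0 with siRNA 1 and below 0 with siRNA 2.

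Single genes also differed between the siRNAs. SPARC was higher with siRNA 2 than with siRNA 1 by 3.72 ± 0.20 log2 units (adjusted p = 1.5e-05), having fallen with siRNA 1 and risen by 1.40 ± 0.18 with siRNA 2. CYP24A1, which encodes the enzyme that inactivates vitamin D, stood at 37.2 ± 1.90 CPM in control, 18.0 ± 0.770 with siRNA 1 and 91.1 ± 4.47 with siRNA 2 (SD, n = 3), a difference of 2.34 ± 0.08 (adjusted p = 7.6e-07). APOBEC3G (3.35 ± 0.27), TNNC1 (2.45 ± 0.38) and RPE65 (2.17 ± 0.14) were higher with siRNA 2, and CD68 (-2.78 ± 0.20), CHAC1 (-2.26 ± 0.16), SLC7A5 (-2.10 ± 0.11) and DDIT3 (-1.78 ± 0.10) were lower. The readthrough gene SPECC1L-ADORA2A was at 0 in all siRNA 2 libraries and at 10.5 ± 0.621 CPM with siRNA 1 (SD), at least 217-fold lower against a floor of 3 counts per library. It also had 0 counts in control replicate 1 beside 408 and 706 in control replicates 2 and 3, so it varied as widely without either siRNA, and its reads cannot be parted from those of SPECC1L and ADORA2A. In all, 2116 genes were higher and 2565 lower with siRNA 2, a balance that turned after GC correction, with 2948 higher and 2682 lower. The count of 4681 was 2130 and 2189 without siRNA 2 replicates 2 and 3, and 2325 in a fit of the siRNA libraries alone.

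10 other lists differed between the siRNAs. G1/S replication was lower with siRNA 2 (13 of 30 lower, 15 adjusted over the list alone, median -0.22, adjusted p = 1.7e-06), with CDC25A at -0.67 ± 0.07 and E2F2 at -0.85 ± 0.09. NRF2 targets were lower (12 of 19 lower and 3 higher, the same counts adjusted over the list alone, median -0.47, adjusted p = 0.00024), with TXNRD1 at -0.77 ± 0.05 and HMOX1 at -0.87 ± 0.09. Cholesterol synthesis (13 of 24 lower; adjusted over the list alone 14 lower and 1 higher; median -0.30, adjusted p = 4.7e-05) and autophagy and lysosome genes (12 of 19 lower and 2 higher, or 13 and 2 adjusted over the list alone, median -0.29, adjusted p = 0.00044) were lower, with DHCR7 at -0.83 ± 0.10 and LAMP1 at -0.44 ± 0.07. Glycolysis was lower (16 of 20, 17 adjusted over the list alone, median -0.32, adjusted p = 5.1e-10; adjusted p = 0.24 with an estimated correlation), with HK2 at -0.67 ± 0.06. Hypoxia targets were lower (13 of 20, 1 higher, or 13 and 2 adjusted over the list alone, median -0.38, adjusted p = 0.00025; adjusted p = 0.093 with an estimated correlation), although SLC2A3 was higher (0.93 ± 0.06). Epithelial genes were lower (10 of 20, 1 higher, or 12 and 2 adjusted over the list alone, median -0.32, adjusted p = 2.2e-05; adjusted p = 0.093 with an estimated correlation), with CLDN7 at -1.31 ± 0.13 and CDH1 at -0.50 ± 0.06. Ribosomal protein genes (18 of 30 lower, 1 higher, or 21 and 1 adjusted over the list alone, median -0.27, adjusted p = 7.6e-07) and oxidative phosphorylation (12 of 25 lower, 2 higher, or 15 and 3 adjusted over the list alone, median -0.30, adjusted p = 0.0013) both had an adjusted p = 0.48 with an estimated correlation. Interferon response genes were higher (11 of 25, 4 lower, or 13 and 5 adjusted over the list alone, median 0.42, adjusted p = 0.012; adjusted p = 0.093 with an estimated correlation), with IFIT1 at 1.53 ± 0.13 and ISG20 at -1.41 ± 0.14. The interferon list was not called without both siRNA libraries numbered 1 (adjusted p = 0.076). With the GC trend removed the 10 medians, in the order given, were -0.27, -0.32, -0.25, -0.18, -0.31, -0.42, -0.33, -0.29, -0.21 and 0.42, all still called.

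Genes that changed in the same direction with both siRNAs included CCND1, which encodes cyclin D1 and fell from 1484 ± 19.4 CPM in control to 819 ± 110 with siRNA 1 and 812 ± 21.1 with siRNA 2 (SD, n = 3), log2 changes of -0.86 ± 0.09 and -0.87 ± 0.09. The tropomyosin gene TPM4 rose from 236 ± 3.39 to 441 ± 37.5 and 424 ± 7.0 CPM (SD), log2 changes of 0.90 ± 0.07 and 0.84 ± 0.07. SCG2 (1.45 and 1.70), HABP4 (1.13 and 1.12), CEMIP, a gene of hyaluronan breakdown (1.02 and 1.43), the kinetochore checkpoint gene ZW10 (0.82 and 0.80) and ILDR2 (1.08 and 0.76) rose with both. KRT7 (-1.70 and -1.08), APOLD1 (-1.48 and -1.19), RPL17-C18orf32 (-1.29 and -1.59), CCN2 (-0.96 and -0.92) and NFKBIA (-0.85 and -0.77) fell with both. Calls that 1 library could end were those of GPATCH4 (1.22 and 1.44), FGF9 (0.74 and 1.15), ZNF616 (0.84 and 0.92) and MOCS2-DT (1.08 and 0.77), and of TNFRSF6B (-1.37 and -1.43), SMAD7 (-1.12 and -1.08), CXCL8 (-0.89 and -0.81) and PILRB (-0.80 and -0.92). The highest adjusted p with siRNA 1 was 0.155 for GPATCH4, 0.0625 for ZNF616, 0.127 for TNFRSF6B and 0.0702 for SMAD7 without control replicate 3, 0.114 for FGF9 and 0.0624 for CXCL8 without control replicate 2, and 0.110 for PILRB without control replicate 1. With siRNA 2 it was 0.0661 for GPATCH4 and 0.0685 for MOCS2-DT without control replicate 3, 0.0573 for CXCL8 without control replicate 2, and 0.0998 for TNFRSF6B and 0.0573 for SMAD7 without siRNA 2 replicate 2. With the GC trend removed, CXCL8 was not called with siRNA 1 (-0.55, adjusted p = 0.074). Other libraries also ended some of these calls, namely the remaining controls and siRNA 1 replicates 1, 2 and 3 or siRNA 2 replicates 2 and 3. TNFRSF6B, PILRB, ZNF616, APOLD1 and RPL17-C18orf32 share exons with genes on the same strand, and HABP4, CEMIP, TPM4, MOCS2-DT, CCN2 and CCND1 overlap genes on the opposite strand.

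In all, 259 genes rose and 189 fell with both siRNAs, and 104 were called in opposite directions. If the siRNAs' calls were independent, 101 genes would share a direction and 102 would not. The log2 changes correlated at 0.356 across genes, which are not independent replicates, but the comparisons share their control libraries. Unchanged groups, with the shared controls simulated too, gave a mean correlation of 0.502. The covariance was 0.144, above the range of 0.113 to 0.126 in the simulated groups. These were drawn from each gene's control mean, so a gene at 0 in the controls could not change in them. They gave 0 shared calls by edgeR in each of 20 runs. Their mean number of calls was only 0.05 for siRNA 1 and 0 for siRNA 2, so shared calls could hardly arise. Over genes with an average log2 CPM of at least 2 the covariance was 0.0175, within the simulated range of 0.0144 to 0.0188, and the correlation 0.144 against a simulated mean of 0.506. Without control replicates 1, 2 and 3 the 448 shared genes were 119, 112 and 128, without siRNA 1 replicates 1, 2 and 3 they were 1089, 251 and 240, and without siRNA 2 replicates 2 and 3 they were 215 and 213. The 104 opposite calls were 23, 20 and 21 without these controls, 238, 63 and 64 without the siRNA 1 libraries, and 295, 37 and 39 without siRNA 2 replicates 1, 2 and 3.

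The average of both siRNAs against control weighs them equally. Of 24 cholesterol synthesis genes 12 fell, 18 adjusted over the list alone (median -0.36, adjusted p = 2.1e-11), and of 20 hypoxia targets 12 fell, 14 adjusted over the list alone (median -0.38, adjusted p = 2.1e-11). Of 15 heat shock genes 8 rose, 11 adjusted over the list alone (median 0.34, adjusted p = 3.5e-11), with HSPA8 at 0.46 ± 0.04. G1/S replication (10 of 30 rose; adjusted over the list alone 21 rose and 1 fell; median 0.25, adjusted p = 5.3e-11), G2/M mitosis (5 of 30 rose, 9 adjusted over the list alone, median 0.15, adjusted p = 1.6e-07) and MYC targets (6 of 30 rose; adjusted over the list alone 10 rose and 1 fell; median 0.15, adjusted p = 1.2e-07) were higher. NF-kB targets (5 of 16 fell, 8 adjusted over the list alone, median -0.47, adjusted p = 3.4e-06), mesenchymal genes (3 of 12 fell, 6 adjusted over the list alone, median -0.29, adjusted p = 0.00065) and TGF-beta and YAP targets (8 of 20 fell and 1 rose, or 11 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.00064) were lower. Lists called here were not all called with each siRNA. With siRNA 2 alone the mesenchymal (median -0.04, adjusted p = 0.53), TGF-beta and YAP (median -0.18, mean 0.23, adjusted p = 0.066) and MAPK output lists (median 0.02, mean -0.12, adjusted p = 0.53) were not called, nor were DNA repair (median 0.19, adjusted p = 0.072), G1/S replication (adjusted p = 0.066) and NRF2 targets (median -0.12, adjusted p = 0.53, against 0.37 with siRNA 1). With siRNA 1 alone glycolysis (median 0.01, adjusted p = 0.92) and the mitochondrial genome (adjusted p = 0.60) were not called. In the average, the mean of the TGF-beta and YAP list was 0.02, of the other sign than its median and test, with ANKRD1 at 0 in the controls, and the median was -0.29 without that gene. Lists whose calls were lost with an estimated correlation were glycolysis (median -0.15, adjusted p = 1.9e-07; adjusted p = 0.25 with an estimated correlation), DNA repair (median 0.18, adjusted p = 0.00040; adjusted p = 0.20 with an estimated correlation) and MAPK output (median -0.11, adjusted p = 0.013; adjusted p = 0.20 with an estimated correlation). The same held for NRF2 targets (median 0.09, adjusted p = 0.013; adjusted p = 0.079 with an estimated correlation) and the mitochondrial genome (median 0.06, adjusted p = 0.038; adjusted p = 0.14 with an estimated correlation), the latter also not called after GC correction (adjusted p = 0.59). The ATF4 list was not called (median 0.01, adjusted p = 0.89). In all, 720 genes rose and 818 fell, of which 32 and 62 changed at least 2-fold. This balance also turned after GC correction (1889 up and 1782 down) and with upper quartile factors (56.2% of the called genes up). The count of 1538 was 371, 314 and 324 without control replicates 1, 2 and 3, 3652, 983 and 942 without siRNA 1 replicates 1, 2 and 3, and 2478, 901 and 886 without siRNA 2 replicates 1, 2 and 3.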

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

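The tests of the ATF4 pattern, of the siRNAs as causes of the GC trend, of the GC trend as a cause of shared calls and of the covariance in abundant genes were chosen after the results were seen.

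The siRNAs target the same RNA, yet 4681 genes and 11 gene lists differed between them in the direct test, and 104 genes were called in opposite directions against control and also between the siRNAs. Without siRNA 2 replicates 2 and 3 the 4681 genes were 2130 and 2189, and a fit of the siRNA libraries alone called 2325. Calls in opposite directions against control were 23, 20 and 21 without control replicates 1, 2 and 3, 238, 63 and 64 without siRNA 1 replicates 1, 2 and 3, and 295, 37 and 39 without siRNA 2 replicates 1, 2 and 3. List medians with siRNA 2 relative to siRNA 1 were -0.22 for G1/S replication, -0.27 for ribosomal proteins, -0.30 for oxidative phosphorylation, -0.32 for glycolysis, -0.38 for hypoxia, -0.30 for cholesterol synthesis, -0.91 for the ATF4 response, 0.42 for the interferon response, -0.32 for epithelial genes, -0.47 for NRF2 targets and -0.29 for autophagy and lysosome genes. With an estimated correlation 5 of these lists were still called, and ribosomal proteins and oxidative phosphorylation (adjusted p = 0.48), glycolysis (0.24) and hypoxia, epithelial genes and the interferon response (0.093) were not. Among single genes the log2 differences were 3.72 for SPARC, 3.35 for APOBEC3G, 2.45 for TNNC1, 2.34 for CYP24A1, 2.17 for RPE65, -2.78 for CD68, -2.26 for CHAC1, -2.10 for SLC7A5 and -1.78 for DDIT3.

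ATF4 targets were higher with siRNA 1 and lower with siRNA 2, the latter with an adjusted p = 0.064 with an estimated correlation. The GC trend does not account for this, since the median between the siRNAs was -0.90 with the trend removed, and neither do the libraries numbered 1 that stood apart, since it was -0.97 without both. The 10 members called in opposite directions, 4, 5 and 4 without control replicates 1, 2 and 3 and 6 without siRNA 2 replicate 2 or 3, describe this pattern and test no cause of it. Effects of either siRNA on other transcripts may contribute and were not tested, since their sequences were not used here, and the siRNAs may also differ in how far they lower EXOSC10-AS1, which the counts are too few to show.

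The trend of expression on GC content set siRNA 1 replicate 1 and siRNA 2 replicates 2 and 3 apart. Genes whose longest transcript is of a non-coding type followed it at 0.837 or more of the correlation seen in protein-coding ones. A GC bias of library preparation would give this. The non-coding set was formed by transcript type, including retained introns, so it can hold protein-coding genes and cannot decide for such a bias. An effect of siRNA 1 is argued against, because a positive trend would be needed in its 3 libraries, and the lowest stood at -0.0813, below the highest control at 0.0465. An effect of siRNA 2 stays open, because its highest library stood at -0.169, below the limit of -0.112 set from the control libraries. A bias of library preparation and an effect of siRNA 2 may both act in the siRNA 2 libraries.

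Genes called in the same direction with both siRNAs are the candidates for a response to the targeted RNA. Over all genes the covariance of 0.144 lay above the simulated range. The simulation drew each gene from its control mean, so genes at 0 in the controls could not change in it. This excess therefore cannot exclude the shared control libraries. Over genes with an average log2 CPM of at least 2 the covariance was 0.0175. It lay within the simulated range of 0.0144 to 0.0188 with the spread of all groups and above 0.00638 to 0.00881 with the spread of the controls. How far the shared controls account for the shared calls thus stays open. After removal of the GC trend, 399 of the 448 genes were still called with both siRNAs. This count cannot decide on the trend as a cause, because the trends ran in opposite directions and would favour opposite calls. The correlations were 0.549 in siRNA 1 replicate 1, and -0.509 and -0.516 in siRNA 2 replicates 2 and 3. Removal also raised the shared calls to 1389, so a gene could stay called whatever its cause. A response to transfection with any siRNA directed at a transcript was not tested, and the low counts of EXOSC10-AS1 leave a link to its loss open.

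The splits of 6 libraries into 3 and 3 number 10 with the real one included, too few for a share under 0.05. Fitted on the groups compared, the real splits called 1420, 4664 and 2325 genes for siRNA 1 against control, siRNA 2 against control and siRNA 2 against siRNA 1, and the highest other splits called 1, 3 and 1, so in each case 1 of 10 splits, the real one, gave as many genes. With both siRNAs as 1 group against control, 3 of 84 splits, the real one included, gave as many genes as the real 180. This share of 0.0357 is under 0.05, but the real split was not the highest, so it does not exclude chance for this comparison. The other 2 gave more, 2729 genes with the siRNA 2 libraries as the group of 3 and 1065 with the siRNA 1 libraries, and point to a structure of the samples. The share therefore shows that libraries group by treatment, and not that the controls stand apart from both siRNAs.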

How the results depend on the processing

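Removal of the GC trend, with length or a block, and the sets of libraries left out together were alternatives chosen after seeing the data. Of 435 results for named genes, 387 were called, of which 254 kept their call and direction under every alternative that gave a value, while 657 of 8692 values lost a call, 74 gained one and 1 turned with a call, PEX14 between the siRNAs at 0.28 with GC and length correction (adjusted p = 0.031). With 1 library left out, 50 of 114 named gene calls were lost with siRNA 1, 44 of 140 with siRNA 2 and 30 of 133 between the siRNAs. Of 40 lists called in the pairwise comparisons 16 kept their call throughout, and 24 of the 38 lost calls were with an estimated correlation. It left 8, 3 and 5 lists called for siRNA 1 against control, siRNA 2 against control and siRNA 2 against siRNA 1, and 9 for the average, which is outside that tally. Fry lost oxidative phosphorylation with siRNA 1 (adjusted p = 0.081) and ribosomal proteins with siRNA 2 (0.072), and the stricter filter lost fatty acid synthesis (0.055) and the mTOR pathway (0.053) with siRNA 2. Between the siRNAs fry called 20 lists and the libraries with a flat GC trend 17. For the counts of genes, no filter gave 969 for siRNA 1 and 281 shared, DESeq2 gave 2704 for siRNA 1, 2493 for the average and 753 shared, fits of only the groups compared gave 4664 for siRNA 2 and 2325 between the siRNAs, and a minimum change of 2-fold gave 173, 340 and 26 for siRNA 1, siRNA 2 and shared. GC correction gave 4077, 4418, 3671 and 1389 for siRNA 1, siRNA 2, the average and shared, and with length 4124, 4523, 3822 and 1459. Without both siRNA libraries numbered 1 these were 5381, 8224, 6895 and 2469, with 7801 between the siRNAs. With a flat GC trend required, siRNA 1, the average and shared gave 5352, 4821 and 1814, with the lone siRNA 2 library assumed to vary like the others. The coefficient of variation was 14.4% and 14.9% in these sets of fewer libraries and 16.8% after GC correction, below that of all libraries uncorrected, and for the other moves the cause was not tested. Leave-one-out counts ran from 439 to 2538 for siRNA 1, 1080 to 4386 for siRNA 2, 2130 to 5843 between the siRNAs, 314 to 3652 for the average and 112 to 1089 shared.

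Pairing of the libraries by replicate number was weak at most. Same-number pairs correlated between -0.0449 and 0.0962 after group means were removed, and other pairs between -0.0711 and 0.0333. Same-number pairs of siRNA 1 with siRNA 2 were all positive, at 0.0962, 0.0488 and 0.0213, and those with a control all negative. A replicate effect shared by the siRNA groups is therefore not excluded. A block for the replicate numbers called 1582, 3311, 5150 and 1559 genes, of which 1292, 2714, 4426 and 1357 were also called without it. GC correction with the block gave 3769, 3350 and 1250 for siRNA 1, the average and shared. EXOSC10-AS1 was not called under any alternative that gave a value for it. DESeq2 and the stricter filter gave none, and for siRNA 1 against control and between the siRNAs neither did fits of only the groups compared. By rule, no value was taken where a group held 3 counts or fewer. This left out, for the same comparisons, the fit without siRNA 1 replicate 1 and both sets of fewer libraries. Their remaining siRNA 1 libraries, replicates 2 and 3, had 0 counts, so whether those fits would call a loss is not given. Alternatives for normalized values were not run because the table holds counts. Depth limits the test of EXOSC10-AS1, at 0 to 26 counts per library.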

Other observations

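Gene families were formed from symbol stems after the data were seen, and all family tests were chosen then. With siRNA 2, 64 of 323 measured zinc finger genes of the ZNF stem rose and 4 fell (median 0.21, camera adjusted p = 2.0e-07 over 175 families; adjusted p = 0.80 with an estimated correlation), and the median was 0.19 with the GC trend removed (adjusted p = 7.0e-08). These genes resemble each other in sequence, so reads can be shared between them. Of 9 genes of the CDKN stem, mostly inhibitors of cyclin-dependent kinases, 5 fell and 1 rose with siRNA 2 (median -0.44, adjusted p = 0.022; adjusted p = 0.80 with an estimated correlation), with CDKN1C at -1.59, CDKN2A at -0.53, CDKN2C at -0.49, CDKN2B at -0.44 and CDKN1A at -0.42 against CDKN3 at 0.44. With the GC trend removed the median of the CDKN genes was -0.28 (adjusted p = 0.019).

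Of 9 keratin genes, 7 fell and 1 rose with siRNA 2 (median -0.40, adjusted p = 0.028; adjusted p = 0.80 with an estimated correlation), including KRT80 at -1.32, KRT7 at -1.08 and KRT15 at -0.92 against KRT23 at 1.18, and the list was not called with the GC trend removed (median -0.27, adjusted p = 0.052). Of 8 SMAD genes, which encode transducers and inhibitors of TGF-beta family signals, 3 fell with siRNA 1 (median -0.36, adjusted p = 0.0025; adjusted p = 0.71 with an estimated correlation), namely the inhibitory SMAD7 at -1.12 and SMAD6 at -0.81 and the transducer SMAD3 at -0.77. The same SMAD genes stood at -1.08, -0.75 and -0.84 with siRNA 2, where the family was not called (median -0.28, adjusted p = 0.20). The SMAD7 call was lost without control replicate 3 with siRNA 1 (adjusted p = 0.0702) and without siRNA 2 replicate 2 with siRNA 2 (adjusted p = 0.0573), among other libraries.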
